A study of Homo sapiens with 6 samples.

How the data were processed

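The series covers 6 sequencing samples of TE-10, a human cell line of the esophageal squamous epithelium derived from a carcinoma. RNA-seq was made from 1 control library and 2 libraries of cells with a stable short hairpin knockdown of METTL3, the catalytic subunit of the complex that writes N6-methyladenosine (m6A) on mRNA. The sample titles number the hairpins 1 and 2, so the knockdown libraries are taken to carry different hairpins. Methylated RNA immunoprecipitation was made from cells with normal METTL3 only, with 1 input library and 2 immunoprecipitated libraries whose labels give different antibody catalogue numbers. Libraries were stranded and made from polyadenylated RNA, per the labels' protocols. Nothing in the labels says whether the libraries came from separate cultures, so limma's p-values for genes measure only the spread between these samples, which may be technical. Camera p-values at the preset correlation, Fisher's tests and ranges of matched draws rest on the spread among genes. They are not evidence over replicate samples.

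Alignment with TopHat2 and counting with HTSeq are named for all samples, and peak calling with MACS2 for the immunoprecipitation, per the submitters' processing notes; versions and parameters are not given in the sources used here. The RNA-seq table holds an expression signal per gene and library whose unit the authors do not state in the deposited header. It lists 18249 genes with 2 decimals, and the columns sum to 608291 in the control, 617840.4 in knockdown 1 and 627152 in knockdown 2. The values are therefore not raw counts or a complete CPM or TPM table. Steps among the lowest values were looked at only in 4 to 6 short receptor genes per library, of like length, so scaling with gene length was not shown. RPKM, FPKM and part of a CPM or TPM table could not be told apart. Sequencing depth is unknown, so no counting interval or floor is given. Symbols matched the reference's current names for 17276 genes and older names for 587, 361 were not matched, and 25 rows whose symbol had been turned into a date were left unnamed.

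The deposited peak list gives 15940 regions with chromosome, start, end, gene, transcript, location class and distance to the annotated start. Its conservation and overlap columns hold no values, and it has no score, fold enrichment or q-value, so peaks could not be ranked by strength. Whether both immunoprecipitations were pooled is not stated. The processing notes name build hg38, but peaks lie beyond the last gene of that build on several chromosomes, for example up to position 249212571 on chromosome 1 where the last gene ends at 248937099, and 16 peaks carry older contig names. Coordinates are given as the file has them, and the build is not taken to be hg38.

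As the table used here holds no counts, the test planned for normalized values was used. Values were transformed to log2(value + 1), genes with a value of at least 1 in at least 1 library were kept (12375 genes), and knockdown was compared with control by limma (version 3.58.1, R 4.3.3) with moderated variances and a mean-variance trend. Adjustment was by Benjamini-Hochberg at 0.05. With 1 control library the spread comes from the 2 knockdown libraries alone, with 1 residual degree of freedom, and the control is assumed to vary like them. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. Data were also simulated with a single spread for all 12375 genes, pooled from the difference of the knockdown libraries, and 200 of the higher genes changed. There the procedure recovered 1% of genes changed 2-fold, 87.5% of genes changed 4-fold and 100% of genes changed 16-fold.

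Of 31 gene lists fixed before the data were examined, 26 had at least 5 tested members and were tested with limma's camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation. In limma the second form uses the residual degrees of freedom, here 1, and the first those of all genes, so a loss of a call between them does not by itself measure correlation among genes. List medians were also placed among 10000 random lists of the same size matched on mean expression. The list of known m6A-marked transcripts holds the symbol TAZ, which in this table is the tafazzin gene. The agreement of the knockdown libraries was compared with 20 simulations of unchanged libraries against a shared control, with the same spread in each library. Peaks annotated to exons or untranslated regions (UTRs) defined genes with a peak, and their fold changes were compared with 10000 expression-matched draws from genes without one. Shares of peaks have 95% Wilson intervals, which cover counting error only. Fisher's exact test was two-sided. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.

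Genes named in the text follow a rule set before the data were examined: the m6A writer complex; Notch receptors, ligands and targets with a mean of at least 1; up to 12 genes per direction past the threshold or, failing that, at least 2-fold changed the same way in both knockdown libraries with a mean above the median of tested genes; and called members, or else the 2 highest, of each other list. 1 gene that the rule takes is not reported here. Genes outside the rule are named as chosen after their values were seen. As the list had no scores, the rule's 10 highest peaks could not be chosen, and as no gene passed the threshold, no called genes with a peak could be named. Alternatives changed the normalization, filter, pseudocount, trend, threshold, gene set correlation, peak definition and matching, or left out a knockdown library. Tests that need counts were not run. m6A in knockdown cells was not analysed here.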

Results

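Expression was measured in 3 RNA-seq libraries of TE-10 esophageal cancer cells, 1 control and 2 METTL3 knockdowns, and m6A sites were mapped in unmodified TE-10 cells by antibody enrichment of methylated RNA. The title of the series places METTL3, m6A and the Notch pathway at the centre of the study. The comparisons below ask which genes differ on knockdown, whether Notch genes are among them, where m6A peaks lie, and whether genes with a peak differ on knockdown. Values are the deposited expression values, given for the control (n = 1) and for each knockdown library or as mean ± SD over both (n = 2).

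METTL3 was lower in both knockdown libraries. Its value was 20.81 in the control, 8.35 in knockdown 1 and 4.99 in knockdown 2, a log2 fold change of -1.54 (SE 0.327). No other member of the writer complex moved alike: METTL14, the partner that binds RNA with METTL3, was at 6.02 and 5.54 ± 0.33, and WTAP, which places the complex in nuclear speckles, at 40.76 and 44.53 ± 6.06. VIRMA was at 4.76 and 3.97 ± 0.54, RBM15 at 2.09 and 2.09 ± 0.65, RBM15B at 18.25 and 19.13 ± 0.25, ZC3H13 at 3.11 and 3.64 ± 0.35, CBLL1 at 6.29 and 7.38 ± 0.09, and METTL16, a separate m6A enzyme, at 5.48 and 5.66 ± 1.29. In limma the adjusted p of METTL3 was 0.0303 adjusted over the list alone, with 1 of 9 members past the threshold, and 1 over all genes tested. The call over the list was lost without the trend (limma adjusted p = 0.0764), with quantile normalization (0.0689) and without the filter on low values (0.388).

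The 5 genes that the naming rule took besides METTL3 were each at least 2-fold different in both knockdown libraries, and none passed the threshold over all genes. ASNS, which makes asparagine, was at 24.01 in the control and 59.84 ± 5.71 on knockdown. The 4 others were lower: the cornified envelope gene SPRR1A (48.91 and 19.05 ± 6.72), the interferon-induced IFI6 (70.91 and 27.93 ± 3.3), the neurotrophin receptor NGFR (43.61 and 18.48 ± 0.33) and the protease inhibitor PI3 of squamous epithelium (242.85 and 107.47 ± 1.85). Of 16 genes that met the 2-fold rule at any level, 4 were higher and 12 lower, METTL3 among them; with a pseudocount of 0.1 they were 91, 56 higher and 35 lower. Chosen after their values were seen, IFI27 was at 16.1 in the control and 2.17 ± 0.47 on knockdown, SPRR2A at 17.09 and 5.34 ± 1.9, and SDC2, a cell surface proteoglycan, at 0.86 and 4.43 ± 0.94. CBSL, SERF1A and DGCR6, also among the 16, have near-identical copies and their values are uncertain. The same holds for SPRR2A, which belongs to a cluster of near-identical genes.

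No gene passed an adjusted p of 0.05 in limma over the 12375 genes tested, and 162 had an unadjusted p under 0.05 where chance gives 619. The test takes its spread from the knockdown libraries and assumes that the control varies like them. Across genes their difference had an SD of 0.505, against 0.279 between knockdown 1 and the control. The test may therefore be too strict, and the lack of calls is not evidence of no effect. In simulated data where all genes shared a single pooled spread, the procedure recovered 1% of 2-fold changes and 87.5% of 4-fold changes. Real genes need not share that spread, and IFI27, at a log2 change of -2.44, did not pass. The simulated shares therefore do not say which changes would be found here.

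**Figure D1:**
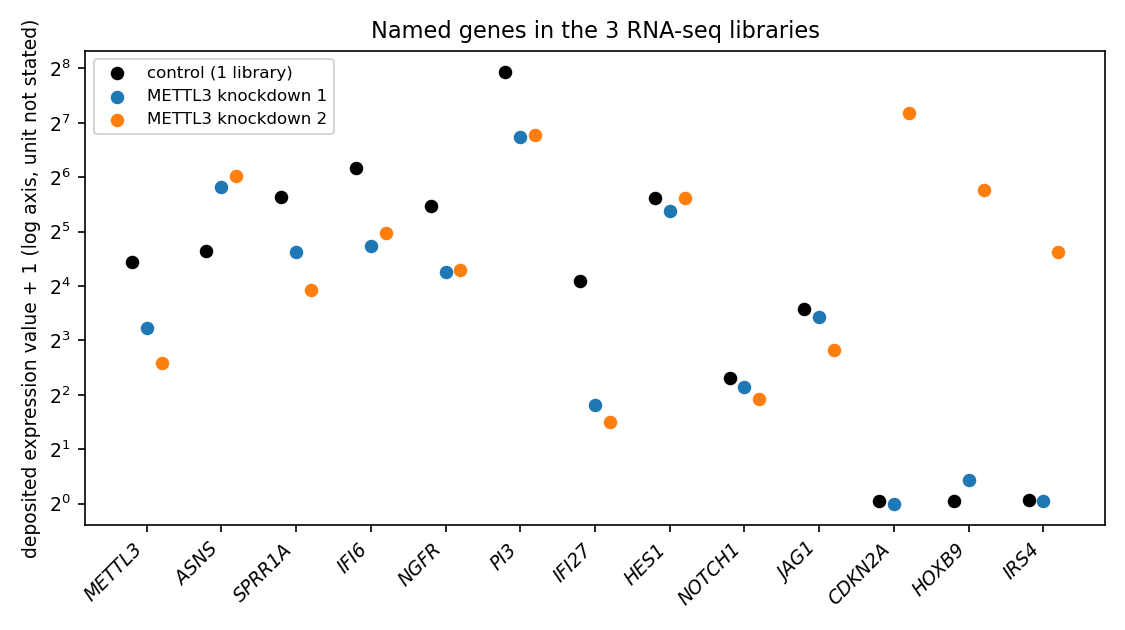
Deposited expression value plus 1 (log axis, unit not stated) of 13 genes in the 3 RNA-seq libraries, 1 point per library. METTL3 is at 20.81 in the control and at 8.35 and 4.99 on knockdown, while CDKN2A, HOXB9 and IRS4 are high in knockdown 2 alone.

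The knockdown libraries differed from each other more than knockdown 1 differed from the control. The cell cycle inhibitor CDKN2A was at 0.04 in the control, 0 in knockdown 1 and 144.68 in knockdown 2. Chosen after their values were seen, the homeobox gene HOXB9 was at 0.03, 0.35 and 53.12 and the insulin receptor substrate IRS4 at 0.05, 0.04 and 23.56. VIM, an intermediate filament of mesenchymal cells, was at 87.02, 88.05 and 311.17. In all, 29 genes were at 5 or more in knockdown 2 and under 0.5 in both other libraries, while no gene was at 5 or more in the control alone or in knockdown 1 alone. Of the fixed list of kidney and HeLa-type markers, 4 were tested, CDKN2A and HOXD13 (6.38, 7.64 and 16.07) being higher in knockdown 2 and PAX8 and GATA3 not. PAX2, WT1 and LHX1 were too low to be tested, and were highest in knockdown 2 (0.78, 0.69 and 0.29).

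Across the 12375 genes, 80 differed at least 2-fold from the control in knockdown 1 (30 higher and 50 lower) and 570 in knockdown 2 (449 higher and 121 lower, or 331 and 185 with quantile normalization), and 645 differed between the knockdown libraries. Fold changes of both libraries against the shared control correlated across genes with Pearson's r = 0.235 and Spearman's rho = 0.249, and 58.46% of genes had the same sign, with genes not being independent replicates. Simulated unchanged libraries with the spread between the knockdowns gave a mean r of 0.504 and a covariance of 0.132, against an observed covariance of 0.0323. With the smaller spread between knockdown 1 and the control they gave r = 0.498 and a covariance of 0.0388. The observed covariance was below both simulated ones. The simulations give each library the same spread, which by itself sets their r. A split of the pairwise differences, with the libraries taken as independent, gave unequal SDs. They were 0.18 for the control, 0.21 for knockdown 1 and 0.46 for knockdown 2. The comparison therefore cannot say whether the knockdowns share effects, and the same limit holds for the simulated counts below. The 4 genes higher and 12 lower in both compare with 1.09 and 0.489 for independent lists, with 6.4 and 7.2 in unchanged libraries at the smaller spread, and with 115.8 and 115.9 at the spread between the knockdowns. The single control could not be split.

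**Figure D2:**
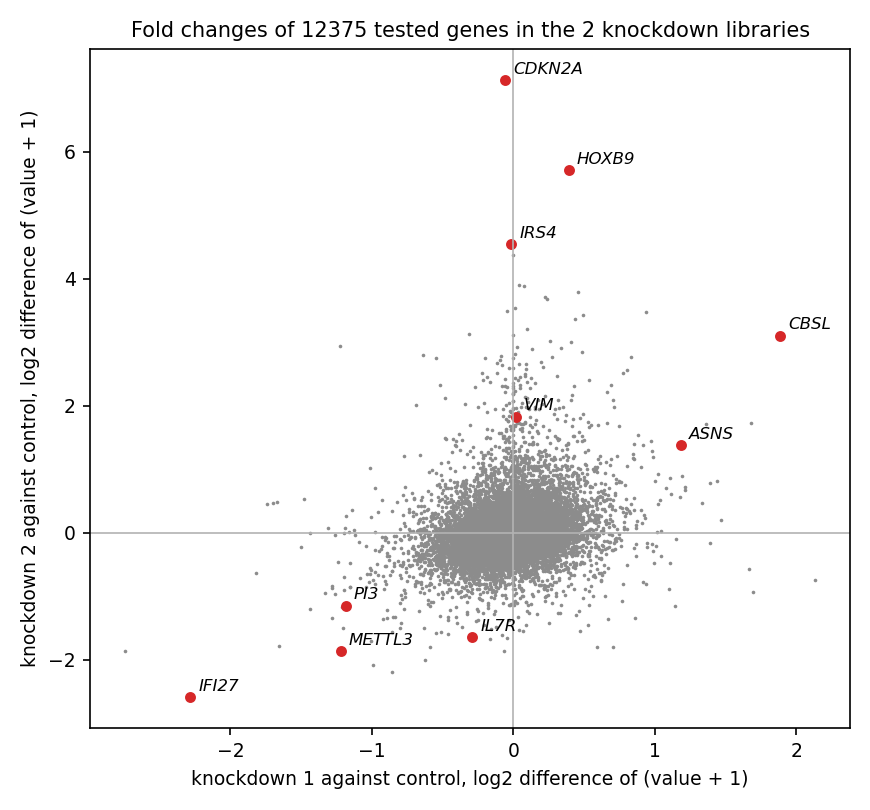
Log2 difference of (value + 1) from the control in knockdown 1 (x axis) and knockdown 2 (y axis) for 12375 genes, 1 point per gene. The cloud is wider along the y axis, where 570 genes differ at least 2-fold against 80 along the x axis, and CDKN2A, HOXB9 and IRS4 lie near 0 on the x axis.

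Notch receptors, ligands and targets did not pass limma's or camera's test. Among receptors, NOTCH1 was at 3.94 in the control, 3.42 in knockdown 1 and 2.81 in knockdown 2, NOTCH2 at 4.15, 4.71 and 5.18, and NOTCH3 at 12.95, 11.85 and 13.38. Among ligands, JAG1 was at 10.97, 9.8 and 6.06, JAG2 at 28.27, 22.58 and 21.19, DLL1 at 1.49, 1.08 and 1.57, DLL3 at 5.45, 6.34 and 6.46, and the related DLK2 at 23.92, 35.89 and 29.04. Of the 8 tested members, 3 were lower and 3 higher in both knockdown libraries, with a median log2 change of -0.07 (-0.13 in knockdown 1 and 0.04 in knockdown 2).

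The target genes split between the libraries. HES1, the best known direct target, was at 48.44 in the control, 40.66 in knockdown 1 and 48.02 in knockdown 2. HEY1 was at 7.57, 5.37 and 22.73, HES4 at 33.2, 29.26 and 81.75, HES5 at 0.47, 0.22 and 6.2, HEY2 at 0.13, 0.44 and 3.46, HES6 at 6.96, 4.7 and 10.26, and NRARP, a feedback inhibitor, at 12.17, 8.16 and 21.41. HES2 (2.14, 0.92 and 2.2) and HEYL (1.98, 1.83 and 2.6) stayed low. MYC was at 25.72, 24.19 and 32.24, CCND1 at 245.47, 230.8 and 168.74, CDKN1A at 67.77, 54.7 and 54.17, SOX9 at 3.56, 3.7 and 1.87, BHLHE40 at 61.72, 52.62 and 42.72, GATA3 at 3.3, 5.23 and 2.32, and IL7R at 10.75, 8.59 and 2.74. The median over 16 targets was -0.24 in knockdown 1 (0.13th percentile of matched random lists), 0.15 in knockdown 2 (92.65th), the library with CDKN2A at 144.68, and 0.05 in the mean of both (73.36th).

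The camera adjusted p was 0.696 for receptors and ligands, 0.673 for targets and 0.265 for processing and nuclear factors, whose highest members were APH1A (129.47, 139.2 and 128.64) and PSENEN (107.42, 133.75 and 98.46). With an estimated correlation these were 0.796, 0.776 and 0.776. No member of the 3 lists passed limma's test over all genes or adjusted over the list alone. Of the 30 processing and nuclear factors, 14 were lower and 6 higher in both libraries. Their median was -0.10 in knockdown 1 (3.94th percentile of matched random lists) and -0.17 in knockdown 2 (1.18th). In the mean of both libraries it was 0.02 (72.83rd).

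Genes of the squamous epithelium were lower on knockdown, by more in knockdown 2. The median log2 change of 20 basal genes was -0.47 (-0.19 in knockdown 1 and -0.68 in knockdown 2), and 13 were lower and 0 higher in both libraries. NGFR passed limma's test adjusted over the list alone (adjusted p = 0.0479), KRT17 was at 1171.05 and 963.54 ± 303.16, and S100A2 at 1127.92 and 880.92 ± 250.91. Of 26 differentiation genes 14 were lower and 3 higher in both, with a median of -0.31 (-0.16 in knockdown 1 and -0.66 in knockdown 2; -0.14 without the filter on low values). SPRR2A and PI3 passed limma's test adjusted over the list alone (lowest adjusted p = 0.0471), while CSTB, the highest of the list, was at 299.59 and 271.54 ± 0.95. These calls over a list, just under 0.05, were not repeated under other settings, and the value of SPRR2A is uncertain. Epithelial junction genes had a median of -0.25 (-0.07 in knockdown 1 and -0.41 in knockdown 2), with JUP at 191.51 and 168.54 ± 30.65 and EPCAM at 179.08 and 141.65 ± 28.46. In knockdown 1 the medians of the basal, differentiation and junction genes lay at the 0.02nd, 0.32nd and 7.74th percentile of matched random lists. The camera adjusted p was 2.38e-07, 3.83e-06 and 0.000238 for the 3 lists at the preset correlation. With an estimated correlation, where camera has 1 degree of freedom, the adjusted p = 0.776 for each. Knockdown 2, where the change was larger, is the library with CDKN2A, HOXB9 and IRS4.

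Interferon-stimulated and inflammatory genes were also lower, by more in knockdown 2. Of 29 interferon-stimulated genes 17 were lower and 3 higher in both libraries, with a median of -0.18 (-0.33 with a mean of at least 5). IFI6 and IFI27 passed limma's test adjusted over the list alone (lowest adjusted p = 0.00428, not repeated under other settings), while the abundant IFITM3 was at 1629.8 and 1314.57 ± 327.71 and BST2 at 402.95 and 293.97 ± 56.43. Of 16 NF-kB and cytokine genes 10 were lower and 1 higher in both, with a median of -0.36. Its highest members were the neutrophil attractant CXCL1 (646.86 in the control, 536.9 and 247.12 on knockdown) and NFKBIA (129.89, 118.59 and 81.11). Camera gave an adjusted p of 1.78e-06 and 0.000137, and an adjusted p = 0.776 for both with an estimated correlation. Medians were -0.11 and -0.16 in knockdown 1 against -0.38 and -0.61 in knockdown 2, the library with CDKN2A at 144.68. Those of knockdown 1 lay at the 6.4th and 1.82nd percentile of matched random lists.

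Genes of the unfolded protein and ATF4 response and of G1/S had higher medians in both libraries. Of 31 response genes 17 were higher and 10 lower in both, with medians of 0.20 in knockdown 1 and 0.14 in knockdown 2. ATF4, the transcription factor of amino acid shortage, was at 397.79 and 642.15 ± 134.7, whereas the calcium-binding chaperone CALR was at 596.4 and 542.97 ± 51.63. Chosen after their values were seen, the serine synthesis genes PHGDH (91.9, 135.48 and 151.34) and PSAT1 (34.04, 78.89 and 64.05) and the glutathione-degrading CHAC1 (4.35, 9.5 and 13.62) were higher in both knockdown libraries, as was ASNS. Of 25 G1/S genes 14 were higher and 1 lower in both, with medians of 0.13 and 0.16; the replication clamp PCNA was at 86.14 and 136.94 ± 18.83, and TYMS at 116.94 and 123.48 ± 20.25. Camera gave an adjusted p of 0.00277 and 0.00329, and an adjusted p = 0.776 for both with an estimated correlation. The response list also lost its call without the filter on low values (adjusted p = 0.133).

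Ribosomal protein genes differed between the libraries, and their call at the preset correlation was not kept with an estimated one on 1 degree of freedom (adjusted p = 0.776) or with quantile normalization (0.321; median 0.03 in place of 0.13). Their median was -0.04 in knockdown 1 and 0.32 in knockdown 2, and 26 of 38 had opposite signs or a change of 0 in a library. RPS2 was at 15009.34 in the control and 15779.65 ± 1736.44 on knockdown, and RPLP1 at 8330.61 and 8367.68 ± 1009.69. The camera adjusted p was 0.0047 at the preset correlation. Knockdown 2, where they were higher, is the library with CDKN2A at 144.68.

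Cholesterol synthesis genes were lower mainly in knockdown 1, with a median of -0.27 (below all matched lists) against -0.05 in knockdown 2 (41.09th percentile). FDPS was at 91.37 in the control, 99.74 in knockdown 1 and 92.36 in knockdown 2. Hypoxia and glycolysis genes had medians of -0.05 and -0.39, with GAPDH at 6857.04, 6867.12 and 5782.87 and ALDOA at 1587.48, 1652.62 and 1294.6. PI3K-AKT and EGFR signalling genes had medians of -0.06 and -0.37, with AKT1 at 253.86, 231.84 and 195.7 and the EGFR ligand AREG at 58.25, 60.97 and 19.24. Stem cell genes had medians of -0.09 and -0.33, with SOX2 at 160.64, 141.05 and 114.16 and CD44 at 72.66, 45.82 and 45.62. Histone genes had medians of -0.15 and -0.16, with H2BC5 at 16.78, 12.67 and 11.93 and H1-2 at 17.08, 16.14 and 18. The camera adjusted p was 0.00287, 2.98e-05, 0.0012, 0.0478 and 0.0435 for these 5 lists, and the adjusted p = 0.776 for each with an estimated correlation. Stem cell genes also lost the call with median-of-ratios scaling (0.0519), equal sums (0.0653), no filter (0.198; median -0.04 in place of -0.21) and a pseudocount of 0.1 (0.0617), and histones with equal sums (0.0515). The lower medians of knockdown 2 in 3 of these lists stand beside CDKN2A at 144.68 in that library. In knockdown 1 their medians lay at the 9.4th (hypoxia and glycolysis), 31.05th (PI3K-AKT and EGFR signalling) and 17.7th percentile (stem cell genes) of matched lists. Histone genes lay at the 9.47th percentile in knockdown 1 and the 4.69th in knockdown 2.

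The other 10 lists tested did not pass. p53 targets had medians of -0.12 in knockdown 1 and 0.38 in knockdown 2, the library with CDKN2A at 144.68 (camera adjusted p = 0.265), with BAX at 77.52, 86.86 and 108.81 and CCNG1 at 53.77, 44.07 and 96.47. NRF2 targets had medians of -0.30 (0.01th percentile of matched lists) and 0.19 (99.39th; 0.673), with FTH1 at 8491.03, 9087.63 and 9853.43 and FTL at 3899.4, 3535.94 and 4134.91. m6A erasers and readers were at a median of 0.11 (0.18 in knockdown 1 and 0.05 in knockdown 2; 0.122), with HNRNPC at 332.63, 378.62 and 344.5 and HNRNPA2B1 at 309.48, 301.44 and 362.7. G2/M genes were at -0.01 (0.01 and -0.03; 0.673), with UBE2C at 280.93, 377.22 and 269.89 and BIRC5 at 115.34, 120.35 and 103.28. Mesenchymal genes were at -0.09 (0.06 and -0.30; 0.403), with TGFBI at 162.76, 142.82 and 84.91; with a mean of at least 5 they were at -0.34 (camera adjusted p = 0.0427, and 0.784 with an estimated correlation) and without the filter on low values at 0.08 (0.874). Immediate early genes were at 0.18 in knockdown 1 and -0.20 in knockdown 2 (0.403), with IER3 at 285.74, 206.56 and 108.97 and JUNB at 58.22, 64.92 and 47.23. The lower medians of these 2 lists in knockdown 2 stand beside CDKN2A at 144.68 there. Wnt targets were at -0.05 and 0.15 (0.619), known m6A-marked transcripts at 0.02 and -0.03 (0.673), with EEF2 at 538.37, 434.85 and 1312.32 and HSP90AB1 at 469.98, 446.65 and 438.49, housekeeping genes at -0.01 and -0.09 (0.769), with RPLP0 at 6021.04, 5929.59 and 5603.2, and the writer complex at -0.16 and 0.05 (0.619). Among fibroblast and blood markers, COL1A1 was at 3.34, 3.6 and 3.59, CD68 at 18.81, 7.88 and 9.93, and HBA1 at 0.56, 0 and 9.81. CD68 passed limma's test adjusted over the 2 tested blood markers alone (adjusted p = 0.0158), a list too small for camera here. None of the 8 endothelial markers reached the filter, and the 15 mitochondrially encoded genes were not among the genes listed.

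**Figure D3:**
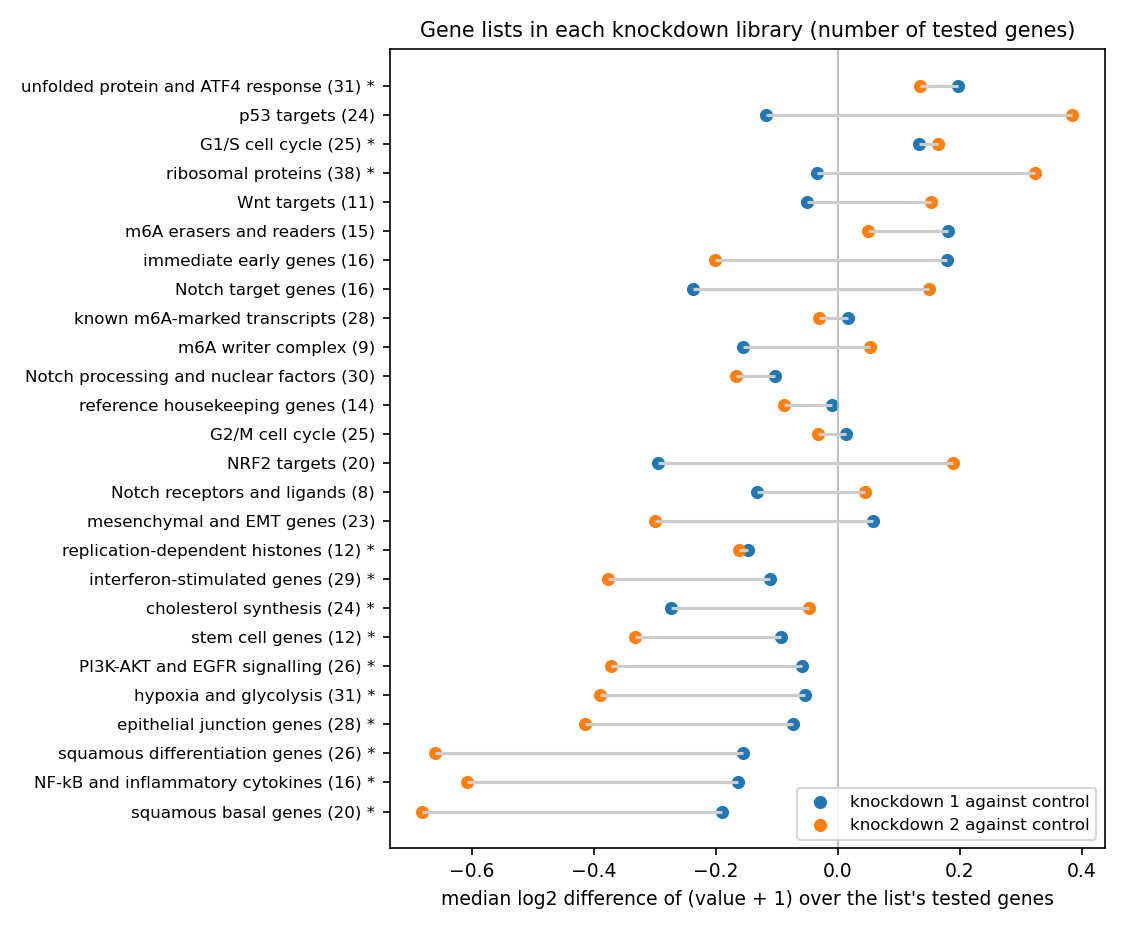
Median log2 difference of (value + 1) from the control over the tested genes of 26 lists, in knockdown 1 and knockdown 2, with the number of genes in parentheses and an asterisk where the camera adjusted p at the preset correlation was under 0.05. With an estimated correlation, on 1 degree of freedom, 0 lists were called (lowest adjusted p = 0.776). Basal squamous genes lie lowest in knockdown 2, at -0.68, and are at -0.19 in knockdown 1.

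m6A peaks lay mainly in exons and UTRs. Of 15940 peaks, 5429 (34.06%, 95% interval 33.33 to 34.8) were in coding exons, 3423 (21.47%) in 3' UTRs, 1842 (11.56%) in 5' UTRs, 3744 (23.49%) in introns, 1249 (7.84%) upstream and 253 (1.59%) downstream of genes. Peaks had a median width of 316 bases. Exonic or UTR peaks fell in 6871 genes, with 13 each in AHNAK2 and FAT1, the most of any gene. Of the genes tested for expression 45.95% had such a peak. In 5 equal groups by expression the share was 41.78% in the lowest group, 53.9% in the next and 32.65% in the highest. Without scores the peaks could not be ranked by strength.

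Notch and writer complex transcripts carried peaks. Of the 8 tested Notch receptors and ligands 7 had an exonic or UTR peak, DLL3 being the exception. Expression-matched genes gave 4.08, with a range of 1 to 7 that includes it. Of 16 targets 9 had a peak, against 7.44 in matched genes (range 4 to 11). In the file's coordinates NOTCH1 had a 3' UTR peak on chromosome 9 from 139389458 to 139389713 and exonic peaks at 139390560 to 139391139 and 139391230 to 139391830. JAG1 had an exonic peak on chromosome 20 from 10620064 to 10620546, JAG2 a 3' UTR peak on chromosome 14 from 105608300 to 105608679, HES1 an exonic peak on chromosome 3 from 193855865 to 193856079, and HEY1 an exonic peak on chromosome 8 from 80677369 to 80678120. Of the 9 genes of the writer complex list, which includes the separate enzyme METTL16, 8 had a peak, METTL3 being the exception. The widest was in RBM15 on chromosome 1 from 110883345 to 110884865.

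Ribosomal protein transcripts had few peaks and immediate early transcripts many. Only RPS24 of 38 ribosomal protein genes had one, where expression-matched genes gave 6.93, and of 14 housekeeping genes 1 did, HPRT1, against 4.23 in matched genes, with a range of 1 to 8 that includes it. Of 16 immediate early genes 14 had a peak, FOS, JUN and EGR1 among them, against 7.37 in matched genes. Matching was on expression alone. Transcript length, which limits the room for a peak, was not taken into account there or in the test that follows. Fisher's exact test, chosen after the counts were seen and adjusted over 26 lists, gave an adjusted p of 1.12e-07 for ribosomal proteins, 0.0102 for immediate early genes and 0.023 for housekeeping genes. Known m6A-marked transcripts were at 0.0489 (20 of 28) and, without TAZ, which in this table is tafazzin, at 0.0753 (19 of 27). Fisher's exact test gave an adjusted p of 0.0753 for the writer complex list, METTL16 included. It gave 0.104 for Notch receptors and ligands and 0.637 for Notch targets.

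**Figure D4:**
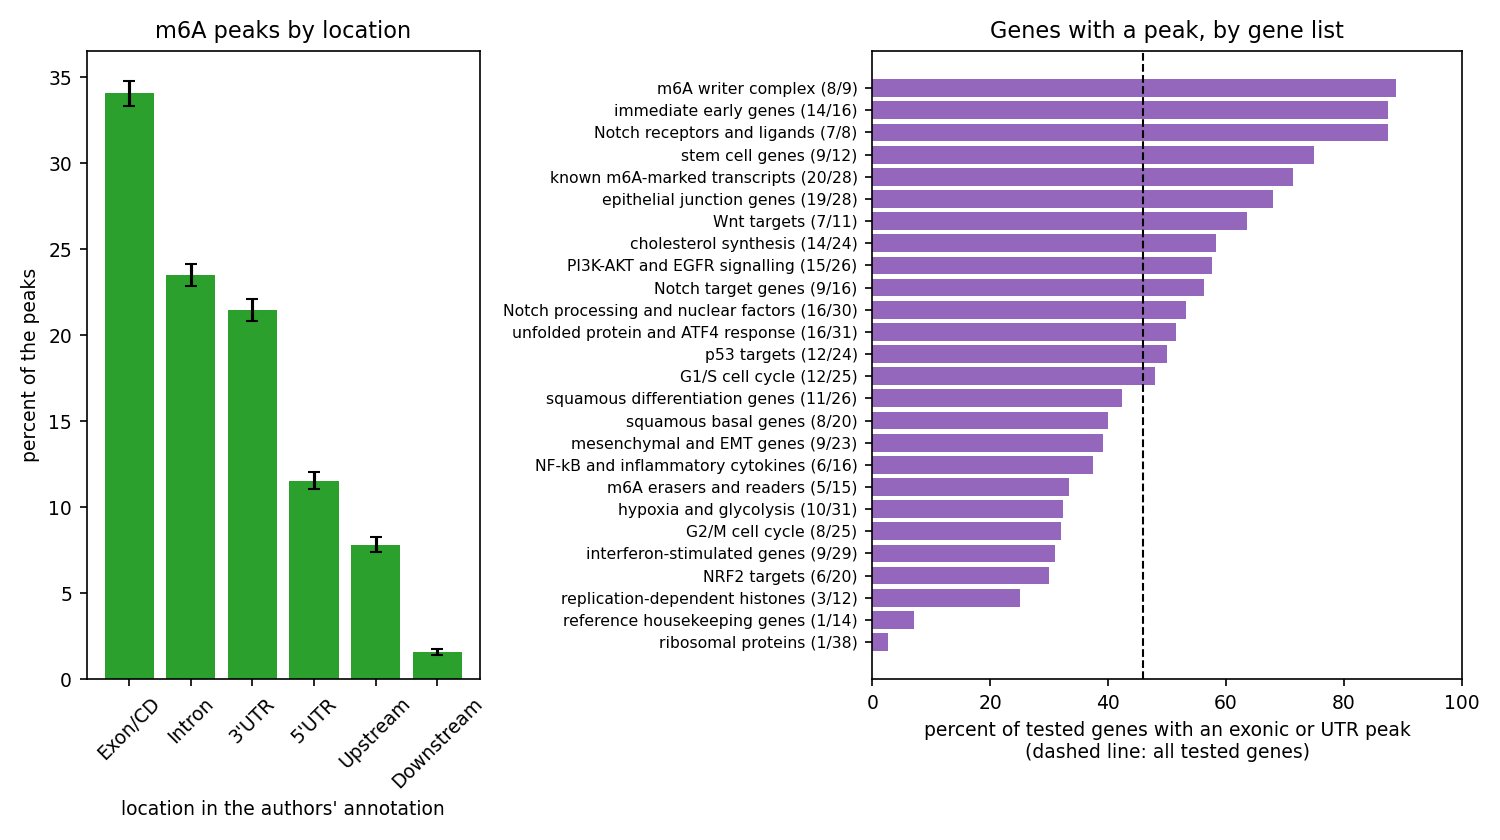
Left, percent of the 15940 m6A peaks in each location class of the authors' annotation, with 95% Wilson intervals. Right, percent of tested genes with an exonic or UTR peak in 26 gene lists, with counts in parentheses and the 45.95% of all tested genes as a dashed line; ribosomal proteins (1 of 38) lie lowest.

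Genes with an exonic or UTR peak lay slightly below matched genes on knockdown. The median log2 change of the 5686 genes with a peak was -0.02, and the difference from matched genes was -0.03 (95% range of draws -0.04 to -0.03), with -0.06 in knockdown 2 (-0.07 to -0.05) and -0.0048 in knockdown 1 (-0.013 to 0.0031; -0.0188 without matching, -0.0243 to -0.0108). Genes with at least 3 peaks lay 0.04 below matched genes in knockdown 1 (-0.0589 to -0.0133), a cut chosen after seeing the data, and for at least 2 peaks the difference there was -0.006 (-0.0194 to 0.0061). Without matching, as median expression went from 10.99 with no peak to 5.69 with 3 or more, medians were 0.02 with no peak, -0.01 with 1, -0.03 with 2 and -0.08 with 3 or more. As a gene set, the 5686 genes had a camera adjusted p of 0.127 at the preset correlation and 0.143 with an estimated correlation. Genes are not independent replicates, and the difference between the libraries was not tested.

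Of the 16 genes at least 2-fold different in both libraries, 4 had an exonic or UTR peak: SPRR1A, NGFR, SPRR2A and PGF. SPRR2A belongs to a cluster of near-identical genes, so its peak is uncertain. With the background limited to genes at or above the 10th percentile of expression of peak genes these were 4 of 13 against 47.2% of other genes (Fisher's exact test, p = 0.277). NGFR had 3 such peaks, 1 in the 5' UTR and 2 in the 3' UTR on chromosome 17, from 47589977 to 47590933 and from 47591238 to 47592007, and SPRR1A 1 on chromosome 1 from 152957591 to 152957847. No gene passed the threshold over all genes, so called genes could not be compared.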

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

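Of the alternatives, the peak widths, the sets of genes with at least 3 peaks, the estimated correlation for peak genes, the m6A-marked list without TAZ, the 2-fold counts per library and the METTL3 test under other settings were chosen after seeing the data. limma called 0 genes under every normalization, filter, pseudocount and threshold tried (123 to 195 with an unadjusted p under 0.05 among settings with the same 12375 genes). The untested rule of a 2-fold difference in both libraries gave 16 genes in place of 0 calls, 91 (56 higher, 35 lower) with a pseudocount of 0.1, and 80 to 570 with 1 knockdown library left out. METTL3 kept its direction under every setting, and its adjusted p over the writer list alone was 0.0764 without trend, 0.0689 with quantile normalization and 0.388 without a filter. The correlation of the knockdown libraries was 0.261 with a mean of at least 5 and 0.217 with a pseudocount of 0.1. All 13 list calls were lost with an estimated correlation, which leaves camera 1 degree of freedom and called 0 lists, also those whose estimated correlation was below the preset one (-0.0267 for G1/S and -0.0323 for the ATF4 response), while other settings called 11 to 14, with mesenchymal genes gained at a mean of at least 5 (adjusted p = 0.0427) and 7 calls lost in all. The median of ribosomal proteins was -0.035 without knockdown replicate 2 and 0.323 without replicate 1. Exonic or UTR peaks were 70.92% of the widest peaks per gene and 72.16% of peaks wider than the median. The difference of peak genes ranged from -0.0595 to -0.0048 with 1 knockdown library left out. The 2-fold rule gave 4 genes with a peak in place of 0. The cause of these shifts was not tested. No paired analysis was possible because the control has 1 library. Count-based tests and the choice of stronger peaks by score could not be run, and depth is unknown.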

Other observations

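The tests of the METTL3 loss, the scaling, the CDKN2A locus, the knockdown 1 share and the library behind the peak-gene difference were chosen after the result was seen. The neuronal marker list was written before its values were seen, and its score over all 11 genes was added after the first result, over the 8 tested ones.

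Around CDKN2A on chromosome 9 the table shows a run of genes near 0 in the control and in knockdown 1. KLHL9 was at 0.06, 0.01 and 2.04 in the control, knockdown 1 and knockdown 2, MTAP at 0.07, 0.03 and 3.31, CDKN2A at 0.04, 0 and 144.68, CDKN2B at 0, 0 and 1.1, and ELAVL2 at 0, 0 and 1.23. HACD4, IFNA21 and DMRTA1 in the run were near 0 in each library. The genes outside the run were present in each library, with FOCAD at 4.13, 3.53 and 5.37 and TUSC1 at 12.02, 15.12 and 9.51.

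Knockdown library 2 stood apart from the other libraries. A scaling difference is argued against by the median difference of all tested genes, 0.012. The 449 genes at least 2-fold higher in knockdown 2 had a median change of 0.057 in knockdown 1, where the ratio of METTL3 changes would give 0.925. For these genes that argues against a response in proportion to the METTL3 change. They were chosen by their value in knockdown 2, however, which favours a small change in knockdown 1. A response to the larger METTL3 loss alone was not tested. For the 121 lower genes a larger loss of METTL3 stays open (-0.223, against -0.813 from the ratio). A candidate explanation is RNA of other cells that kept the CDKN2A locus, which 3 of 3 genes there (MTAP, CDKN2A and CDKN2B) prompted and so cannot test; an effect of the second hairpin on other genes is open and untested as well. Whether cells of the HEK293 type, a kidney-derived line, are present cannot be told apart from other sources, since the 8 tested neuronal markers passed their bound (median 0.745, 99.75th percentile of matched lists) but the filter drops markers for being low in knockdown 2, and all 11 just missed it (0.215, 97.19th), with CRMP1 at 2.39 and ZIC2 at 13.84 in knockdown 2 against NES at 0.26 and SOX11 at 0.01. The 4 tested kidney and HeLa-type markers, CDKN2A among them, had a median of 0.527 (99.01st percentile), with 2 higher in knockdown 2. The filter kept CDKN2A for its value in knockdown 2 alone. It dropped PAX2 (0.01, 0 and 0.78), WT1 (0.02, 0.02 and 0.69) and LHX1 (0, 0 and 0.29), low genes that were each highest in knockdown 2. Without the filter the median change of 7 markers from the control was 0 in knockdown 1 and 0.728 in knockdown 2. PAX8 and GATA3 were not higher there, and no matched bound was drawn for the 7.

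Genes with an m6A peak lay lower than matched genes, mainly in knockdown 2. The difference in knockdown 1 was -0.0048, and -0.0072 (-0.0153 to 0.0007) with matching on gene span as well, both with ranges that include 0. Without matching it was -0.0188 (-0.0243 to -0.0108), which leaves differences in expression in. A range that includes 0 does not exclude a small difference. Whether the difference could come from knockdown 2 alone therefore stays open. Genes with at least 3 peaks do not settle it: their difference in knockdown 1 was -0.0358 (-0.0589 to -0.0133), but that cut was chosen after seeing the data and the planned set of at least 2 peaks gave -0.006 (-0.0194 to 0.0061). Without genes at least 2-fold different between the knockdown libraries, the difference in knockdown 2 was -0.0522 (-0.0615 to -0.0436), against -0.0595 with them. Of the 5686 genes with a peak 5484 stayed, and a median moves little when so few are left out. The comparison therefore cannot decide whether those genes are its source. Shifts below 2-fold stay in that comparison, so RNA of other cells in knockdown 2 stays open as a source. Genes with a peak had medians of -0.0243 in knockdown 1 and -0.0307 in knockdown 2, and matched genes -0.0195 and 0.0288. A loss of m6A as the cause stays open, as methylation on knockdown was not analysed here.

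Squamous genes lay lower in knockdown 1 as well, with a median of -0.19 for basal genes. Other cells of the kind in knockdown 2 are argued against as the cause there: the 35 genes under 0.5 in the control and at 5 or more in knockdown 2 were in knockdown 1 at a median of 1.54% of their level in knockdown 2. METTL3 loss and other differences between cultures stay open.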
